A study of Mus musculus with 8 samples.

How the data were processed

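RNA bound to tagged ribosomes of 8 mouse hippocampi was measured on 1-colour Agilent mouse arrays, 1 array per mouse, with 4 WT and 4 CKO mice. Per the labels' protocols the RNA was amplified by whole transcriptome amplification and labelled with Cy5. The deposited scanner files give a spot intensity for the red channel, and per the file headers they came from Agilent Feature Extraction with spatial and multiplicative detrending; version 11.5 is given in the submitters' processing notes. Its processed signal is the background-subtracted intensity, set to a small positive surrogate value where it would fall near or below 0. Per the file headers probe coordinates are those of mm9. The authors also deposited a table of values per spot, an intensity on a linear scale. Within each array its ranks followed the background-subtracted signal, with a Spearman correlation that rounds to 1. It was blank for 7359 to 11803 spots per array, and its medians were 1309, 1313, 1263 and 1645 for WT 1 to 4 and 1507, 1362, 1987 and 1561 for CKO 1 to 4. Its centring and the authors' normalization between arrays are not given in the sources used here.

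Groups and replicate numbers were taken from the sample titles, and sex from the labels. The mice are labelled as biological replicates. Of 62976 spots 59305 were not controls. Spots flagged as outliers were left out, spots of one probe were averaged on the log2 scale, and 18 of 55681 probes had no unflagged spot on some array. No spot was saturated. Log2 of the processed signal was taken minus each array's 75th percentile. The 44316 probes well above background on at least 4 of the 8 arrays were kept, and each gene was represented by its probe with the highest mean, which gave 29529 genes. Names came from the accession of each probe through a table of the GRCm38.p6 assembly, used for names alone. It matched 28331 probes, and the file's name was kept for the others. Of the genes tested 16565 have a gene symbol. A gene not well above background on any array of 1 group has only a bound there. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

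Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Ctcf also had an exact permutation test over 35 distinct splits. The 33 gene lists, the test of each comparison and the rule for named genes were fixed before the data were examined. The lists held 827 genes, of which 711 were measured, and 31 of these were in over 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation and with fry. The rule named Ctcf and, in each direction, up to 15 genes past the threshold with the largest differences or, with fewer than 10 past it, the 10 with the smallest unadjusted p. These had to have a symbol, groups that do not overlap and signal well above background on all 8 arrays. From each list it took the members past the threshold adjusted over the list alone, up to 6, or otherwise the 2 with the smallest p. Some genes that the rule takes are not reported here.

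The fit was tested on simulated data with the real genes' means and spreads, in the comparison of CKO with WT over 29529 genes. Of 100 genes changed by 1 on the log2 scale 17 were recovered, and of 100 changed by 2, 86 were, with 7 false calls among unchanged genes. A list shifted by -0.4 was recovered, and no other list was called. The simulated genes were drawn independently, with no correlation between genes and no slides. The simulation therefore cannot show how often camera calls unchanged lists in the real arrays. To set list medians against signal, 10000 random lists matched on mean signal were drawn for each list.

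Alternatives were median scaling, quantile normalization, normexp background correction with an offset of 50 and quantile normalization, the authors' deposited values (log2), no filter on dim probes, probes well above background on all 8 arrays, the mean of a gene's probes, a test of each probe, a trended and robust prior variance, array weights, the slide as a fixed or random block and within each slide, sex as a covariate, males only, the replicate number as a block, and each array left out. The normexp offset is added to every intensity before log2, which by itself shrinks the differences of dim genes. Smaller differences of dim genes with that setting can be in part a result of the offset. Quantile normalization with the slide as a block was added after seeing the data. Immunoprecipitation input RNA was not analysed here.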

Results

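The series measured RNA bound to tagged ribosomes of the hippocampus, in control mice and in conditional knockouts of the gene for CTCF. CTCF is a zinc finger protein that binds DNA and shapes chromosome loops. In the RiboTag method a Cre recombinase switches on a haemagglutinin-tagged copy of the ribosomal protein Rpl22, and the tagged ribosomes are pulled down with their transcripts. Here the Cre was driven by Camk2a, which is active in forebrain excitatory neurons. The study's title names microglia and inflammation-related transcription as its subject. There were 8 arrays, 1 per mouse: 4 of the WT group, labelled wild type for Ctcf and positive for Cre and RiboTag, and 4 of the conditional knockout (CKO) group, labelled homozygous for the loxP allele of Ctcf and positive for both. The series' design text instead describes the controls as loxP homozygotes, and the sample labels were followed. Each group held 3 males and 1 female, all at least 3 months old.

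Between 72.2% (CKO 3) and 81.5% (WT 1) of the 55663 probes used were well above background. The other arrays lay between 77.2% and 80.8%. Xist, the RNA that coats the inactive X chromosome, and the Y-linked Ddx3y matched the labelled sex of all 8 mice. The arrays lay on 3 slides, with WT 1 on slide 1, WT 2, WT 3, CKO 1 and CKO 2 on slide 2, and WT 4, CKO 3 and CKO 4 on slide 3. The first principal component of the gene values held 54.4% of the variance. It placed the 3 arrays of slide 3 between 29.6 and 128, with CKO 3 farthest out, and the 5 others between -67.4 and -14.6. No 2 arrays were copies of each other, and the highest correlation between arrays was 0.986 (WT 3 and CKO 2). The number of arrays limits the precision of every value.

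Ctcf signal was lower in all 4 CKO mice than in any WT mouse, at a normalized log2 signal of -2.24 ± 0.29 (SD, n = 4) against -1.37 ± 0.30 (SD, n = 4). The log2 difference was -0.87 with a standard error of 0.22, which left 54.8% of the WT signal. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 mice against 4 allow. Over all genes tested limma gave an adjusted p of 0.724, so Ctcf did not pass the threshold of 0.05. The difference was -0.57 with normexp background correction and quantile normalization, -0.86 with the slide as a block, -0.88 within slide 2 and -0.84 within slide 3, and slide 1 held 1 WT array alone. The single Ctcf probe lies on chromosome 8 at 108206632 to 108206691 of the mouse build mm9. The labels do not say which exons the loxP sites flank, so whether the probe lies in the deleted part is not known here.

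**Figure D1:**
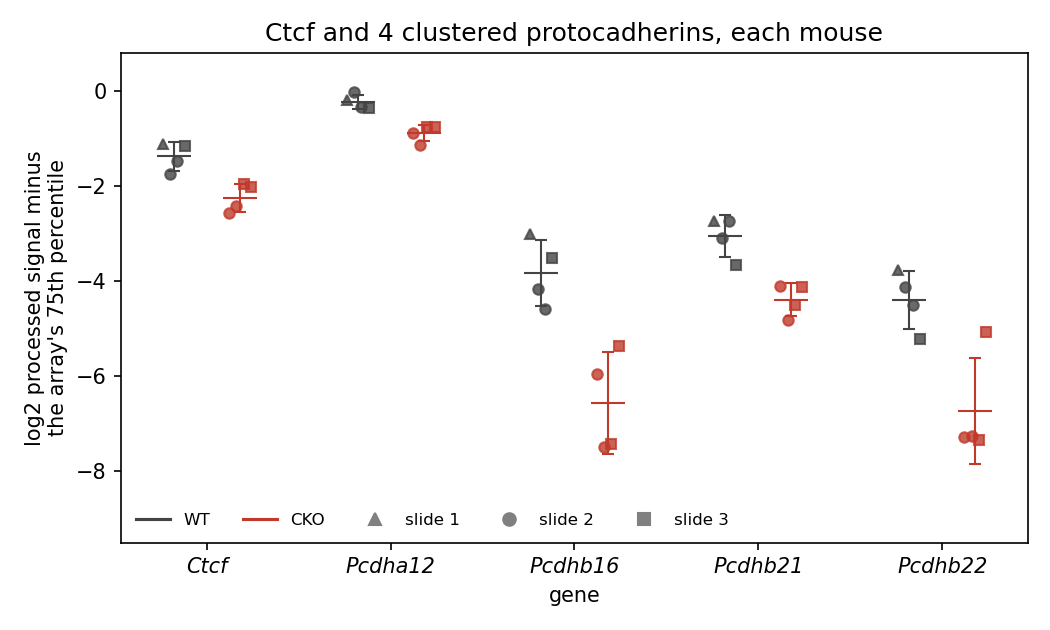
Normalized log2 signal (vertical axis, log2 processed signal minus each array's 75th percentile) of Ctcf and 4 clustered protocadherins in each mouse, with WT in grey and CKO in red and a marker shape per slide; horizontal bars are means and whiskers SD (n = 4). For Ctcf the WT mean was -1.37 and the CKO mean -2.24, and the groups did not overlap for Ctcf, Pcdha12, Pcdhb16 and Pcdhb21, while for Pcdhb22 the CKO 4 value of -5.06 lay above the lowest WT value.

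The comparison of genotypes across all genes asked which transcripts bound by tagged ribosomes differ between CKO and WT mice. Of 29529 genes tested with limma, 1 passed an adjusted p of 0.05, and it was lower in CKO. It was named after its values were seen, since it has only a transcript name in the files, ENSMUST00000103598, at 53576868 to 53576927 on chromosome 14 (mm9). Its probe was well above background on all 4 WT arrays and on 0 of the CKO arrays, so with 75th percentile scaling the signal was at least 4.00-fold lower in CKO (adjusted p = 0.0309). With normexp background correction and quantile normalization its log2 difference was -0.72, short of that bound, and its adjusted p was 0.375. With quantile normalization alone it was -2.45, with an adjusted p of 0.417, and over the alternatives the adjusted p of ENSMUST00000103598 ran from 0.00387 to 0.526. No gene was higher in CKO past the threshold. At an unadjusted limma p under 0.05, 738 genes were higher and 829 lower, against 1476 that chance alone gives. The balance moved with the scaling, to 758 higher and 511 lower with quantile normalization, 907 and 502 with normexp and quantile normalization, and 1032 and 325 with the authors' own values. The counts also moved, to 708 higher and 1112 lower with the slide as a block and 2008 and 2669 with array weights. Without WT 4 they were 1556 and 2384, and without CKO 3 they were 338 and 526. With the slide as a block 1 gene passed, within slide 2 none and within slide 3 1 gene, higher in CKO. Slide 3 holds WT 4 alone against 2 CKO arrays, so the spread there is that of all arrays within their slide and genotype, with 3 residual degrees of freedom, and WT 4 is assumed to vary like the others. With quantile normalization 0 genes passed, with normexp background correction and quantile normalization 3 were higher (Mnd1, Nmbr and 1 other) and 1, Pdf, was lower, and without CKO 3 none passed. The values of 980 genes, 3.32%, did not overlap between the groups, where chance gives 2.86%.

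The genes named next were taken by a fixed rule, and none of the 20 passed the threshold with 75th percentile scaling and all arrays. The rule itself required that all 4 CKO values of each lay on one side of the 4 WT values. Of the 25 alternatives Mnd1 passed in 6 and Nmbr in 5, Etfdh and Pdf in 3 each, Egfl6 and Trim36 in 2 each, and Tnfrsf12a and Zfhx3 in 1 each. The 10 genes higher in CKO with the smallest unadjusted p were led by Mnd1, a meiotic recombination protein, whose log2 difference was 3.18 ± 0.36 (SE) with a limma adjusted p of 0.0895. Nmbr, the neuromedin B receptor, differed by 2.27 (SE 0.28, limma adjusted p = 0.104). Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, differed by 1.88 (SE 0.25) and Egfl6 by 1.44 (SE 0.19), both with a limma adjusted p of 0.117. The others were Trim36 at 1.42, Eya2 at 1.06, the chemokine Ccl17 at 1.03, Tnfrsf12a, the receptor of the cytokine TWEAK, at 1.01, Ccdc113 at 0.97 and Cpne1 at 0.88, with limma adjusted p between 0.147 and 0.542. A second probe of Mnd1 differed by 5.84, and one of Cpne1 by 0.26. Etfdh lies at 79407806 to 79407865 on chromosome 3, and Ccl17 at 97335770 to 97335829 and Ccdc113 at 98082729 to 98082788 on chromosome 8 (mm9).

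Among the 10 genes lower in CKO, Pdf, a mitochondrial peptide deformylase, had a log2 difference of -1.22 (SE 0.18, limma adjusted p = 0.198). Zfhx3, a homeobox transcription factor, differed by -2.24 (SE 0.43, limma adjusted p = 0.542), and Pcdhb21, a clustered protocadherin, by -1.33 (SE 0.26, limma adjusted p = 0.573). The remaining values were -1.09 for Tpbg, -0.87 for Hddc3, -0.85 for Fndc1, -1.09 for Chst12, -0.94 for Lratd2, -1.05 for Foxq1 and -0.89 for Brinp3, with limma adjusted p from 0.532 to 0.724. With normexp background correction and quantile normalization these shrank to -1.097 for Zfhx3, -0.46 for Pcdhb21, -0.72 for Tpbg, -0.31 for Chst12, -0.50 for Lratd2, -0.55 for Foxq1 and -0.30 for Brinp3. A second probe of Fndc1 differed by -0.43. Pdf lies at 109570205 to 109570264 and Zfhx3 at 111485354 to 111485413 on chromosome 8 (mm9).

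Gene lists fixed in advance were then tested with camera, which asks whether a list's genes shift relative to the other genes, whose median log2 difference was -0.078. With a preset correlation of 0.01 between genes, 14 of 33 lists passed an adjusted p of 0.05, 13 of them higher and 1 lower in CKO. With the correlation estimated from the data 0 lists passed, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.202. Of the 14 lists 9 kept their call and direction with the slide as a block, and 9 did with quantile normalization. The differences also followed signal. The median log2 difference ran from -0.52 in the dimmest of 10 equal groups of genes to 0.16 in the brightest, and quantile normalization brought these to -0.067 and 0.026. Adjusted over the list alone 9 genes passed, and over all genes tested none of them did. In each of the 13 lists called higher at most 3 of the 4 CKO mice had a median signal above every WT mouse. For oligodendrocytes, voltage-gated channels, and unfolded protein and integrated stress 0 had. In the list called lower, the clustered protocadherins, the medians of all 4 CKO mice lay below every WT mouse.

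The clustered protocadherins, cell-surface adhesion proteins encoded in tandem on chromosome 18, were the list that was lower in CKO. Of 28 measured members 24 had a negative difference, and the median was -0.38 (camera adjusted p = 5.11e-07; adjusted p = 0.202 with an estimated correlation). Over all genes tested with limma 0 members passed, with 9 lower and 0 higher at an unadjusted p under 0.05. Adjusted over the list alone 4 fell, 0 rose and 24 did not pass. These 4 were Pcdhb16 (-2.74, SE 0.54), Pcdhb22 (-2.34, SE 0.54), Pcdhb21 (-1.33, SE 0.26) and Pcdha12 (-0.65, SE 0.16), with limma p adjusted over the list alone of 0.00956, 0.0170, 0.00956 and 0.0197. Pcdhb16 and Pcdhb22 were well above background on 1 CKO array and 4 WT arrays each. With normexp background correction and quantile normalization the differences shrank to -0.60 for Pcdhb16, -0.34 for Pcdhb22 and -0.46 for Pcdhb21. The list's median was -0.22 there and -0.17 with the authors' own values, and the list passed as lower with both. The list's median was -0.39 with the slide as a block, -0.33 within slide 2 and -0.36 within slide 3. Pcdhb16 lies at 37642126 to 37642185, Pcdhb21 at 37675857 to 37675916, Pcdhb22 at 37680669 to 37680728 and Pcdha12 at 37182217 to 37182276 on chromosome 18 (mm9).

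Of the inflammation lists, which the study's title points to, antigen presentation passed the camera test and the others did not. Antigen presentation was higher in CKO, with a median of 0.072 over 21 genes (adjusted p = 0.0394; adjusted p = 0.555 with an estimated correlation). Its median was 0.11 with the slide as a block, 0.11 within slide 2 and 0.13 within slide 3. Psmb10, an immunoproteasome subunit, differed by 0.43, and Psmb8, another, by 2.72 with signal well above background on 1 WT and 3 CKO arrays, and neither passed adjusted over the list alone. Psmb8 differed by 0.78 with normexp background correction and quantile normalization. The Psmb10 probe lies at 108459677 to 108459736 on chromosome 8 (mm9), close to Ctcf. The hypothesis given below for genes near Ctcf therefore covers Psmb10 too. Cytokines and chemokines had a median of -0.16 over 27 genes (camera adjusted p = 0.749). Ccl17 rose by 1.03 on the log2 scale with a limma p of 0.0130 adjusted over the list alone, and 26 members did not pass. The interferon response had a median of -0.22 over 30 genes (adjusted p = 0.476), with Ifitm3 at 0.66 and Ifit2 at -0.73. NF-kB targets had -0.025 over 18 (adjusted p = 0.834), with Bcl3 at -0.74 and Sod2 at 0.30, and complement 0.022 over 17 (adjusted p = 0.215), with Clu at 0.54 and C4b at 0.47. Complement passed as higher without CKO 3, with a median of 0.14. None of these 6 named members passed either adjustment.

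Markers of other brain cells were measured because an immunoprecipitate can also hold their RNA. Oligodendrocyte genes, whose products build myelin, were higher in CKO with a median of 0.18 over 22 genes (camera adjusted p = 0.00537; adjusted p = 0.605 with an estimated correlation). The median was 0.30 with the slide as a block, 0.34 within slide 2 and 0.30 within slide 3. By mouse the list's median signal was highest in WT 1 (0.098) and next in CKO 4 (0.050). CKO 1 (-0.31) and CKO 3 (-0.35) lay among the WT mice, which ran from -0.55 to 0.098. Enpp2 differed by 0.66 and Mal by 0.68. Astrocyte genes were higher with a median of 0.16 over 23 genes (adjusted p = 0.00866; adjusted p = 0.555 with an estimated correlation), and their median was 0.21 with the slide as a block, 0.27 within slide 2 and 0.054 within slide 3. Aldoc differed by 0.48 and Mlc1 by 0.71, and no gene of either list passed adjusted over the list alone. The microglia list did not pass, with a median of 0.081 over 31 genes (adjusted p = 0.0960), with Laptm5 at 0.55 and at 0.19 by a second probe. It passed as higher with the slide as a block (median 0.084), with quantile normalization (0.16) and without CKO 3 (0.12). It also passed with normexp background correction and quantile normalization (0.11) and with the authors' own values (0.18). Median scaling (0.17) and an estimated correlation (camera adjusted p = 0.731) did not call it. Its median was 0.20 within slide 2, 0.040 within slide 3 and -0.028 without WT 4. With all arrays its median lay at the 99.9th percentile of signal-matched random lists.

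Disease-associated microglia genes had a median of 0.054 over 19 genes (camera adjusted p = 0.425), with Cd63 at 0.67 and Lilrb4a at -0.70. Reactive astrocyte genes had 0.0058 over 24 (adjusted p = 0.749), with Emp1 at 1.53. Oligodendrocyte precursor genes had -0.10 over 15 (adjusted p = 0.600), and 0.22 within slide 2, where they passed as higher. Adjusted over that list alone C1ql1 rose (1.02) and Neu4 fell (-1.59), each with a limma adjusted p of 0.0240, and Neu4 was well above background on 1 CKO array. Neu4 differed by -0.17 with normexp background correction and quantile normalization, with an unadjusted limma p of 0.190, so it no longer passed. Choroid plexus and ependyma genes had 0.030 over 13 (adjusted p = 0.0663), with Ttr, the thyroid hormone carrier transthyretin, at 1.16 and Kl at 0.43, and passed as higher with the slide as a block (median 0.066) and with quantile normalization (0.19). Endothelium and pericytes had -0.061 over 26 (adjusted p = 0.834), with Itm2a at 0.77 and Pecam1 at -0.85. Blood genes had 0.14 over 7 (adjusted p = 0.834), with Slc4a1 at -0.32 and Ahsp at -0.42.

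Of the hippocampal neuron lists, CA1 genes were higher with a median of 0.25 over 12 genes (camera adjusted p = 0.00537; adjusted p = 0.637 with an estimated correlation), with Fibcd1 at 0.46 and Mpped1 at 0.31. Their median was 0.21 with the slide as a block, where they no longer passed, 0.22 within slide 2 and 0.057 within slide 3, and they did not pass with quantile normalization or without CKO 3. Dentate gyrus genes had a median of -0.16 over 18 (adjusted p = 0.0960), with Tdo2 at -0.72 and Calb1 at -0.84. They passed as lower with the slide as a block (-0.30), with quantile normalization (-0.19) and without CKO 3 (-0.27), and had -0.20 within slide 2 and -0.35 within slide 3. CA2 genes had -0.058 over 10 (adjusted p = 0.836), with Amigo2 at -0.75 and Plcxd3 at -1.01, well above background on 3 and 2 CKO arrays. Amigo2 had -0.050 and Plcxd3 -0.13 with normexp background correction and quantile normalization. CA3 genes had 0.14 over 13 (adjusted p = 0.402), and Cdh24 fell by 0.77 on the log2 scale with a limma adjusted p of 0.0330, adjusted over the list alone. Excitatory neuron genes had 0.057 over 21 (adjusted p = 0.0869), with Nrgn at 0.59 and Fezf2 at -0.37. Interneuron genes had 0.0050 over 21 (adjusted p = 0.247), with Pvalb at 0.55 and Tac1 at 1.71, and passed as higher with the slide as a block (median 0.12).

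Among lists of neuronal function, synapse genes were higher with a median of 0.17 over 41 genes, 37 of them above 0 (camera adjusted p = 1.27e-04; adjusted p = 0.555 with an estimated correlation), with the synapsins Syn1 at 0.48 and Syn2 at 0.40. Their median was 0.11 with the slide as a block, 0.12 within slide 2 and 0.052 within slide 3. Activity-regulated genes were higher with 0.17 over 35 (adjusted p = 0.00754; adjusted p = 0.731 with an estimated correlation), with Vgf at 0.41 and Homer1 at 0.47, and without CKO 3 their median was -0.027. They had 0.11 with the slide as a block, where they no longer passed, 0.081 within slide 2 and 0.032 within slide 3. Neuropeptides were higher with 0.13 over 20 (adjusted p = 0.0280; adjusted p = 0.555 with an estimated correlation), with Chgb at 0.33. They had 0.12 with the slide as a block, where they no longer passed, 0.091 within slide 2 and 0.18 within slide 3. Voltage-gated channels were higher with 0.070 over 39 (adjusted p = 0.0499; adjusted p = 0.679 with an estimated correlation), but turned to -0.019 with the authors' own values and to -0.026 without CKO 3, and their test turned to lower with normexp and quantile normalization. They had 0.0013 with the slide as a block, where they no longer passed, 0.054 within slide 2 and -0.021 within slide 3, with Scn2b at 0.69. None of these 4 lists passed with quantile normalization, and 0 of their genes passed adjusted over the list alone. In the same arrays the oligodendrocyte and astrocyte lists were also higher.

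Sterol synthesis genes were higher with a median of 0.30 over 22 genes, 20 of them above 0 (camera adjusted p = 4.16e-06; adjusted p = 0.555 with an estimated correlation), with Hmgcs1, an enzyme of the mevalonate pathway, at 0.52 and Stard4 at 0.82. Their median was 0.23 with the slide as a block, 0.21 within slide 2 and 0.23 within slide 3. Cytosolic ribosomal proteins were higher with 0.25 over 34 genes, 32 of them above 0 (adjusted p = 3.59e-09; adjusted p = 0.555 with an estimated correlation), with Rps9 at 0.49 and Rps24 at 0.37. They had 0.22 with the slide as a block, 0.26 within slide 2, 0.13 within slide 3 and 0.13 with quantile normalization, and did not pass with the authors' own values (0.094). Mitochondrial respiration genes were higher with 0.21 over 30 genes, all 30 above 0 (adjusted p = 5.11e-07; adjusted p = 0.555 with an estimated correlation), with Cycs, cytochrome c, at 0.44 and Ndufb8 at 0.33. They had 0.14 with the slide as a block, 0.19 within slide 2, 0.11 within slide 3 and 0.080 with quantile normalization. They did not pass with the authors' own values (0.028) or with quantile normalization and the slide as a block (0.053), and their median lay at the 87.3rd percentile of signal-matched random lists.

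Targets of p53 were higher with a median of 0.18 over 20 genes (camera adjusted p = 0.0160; adjusted p = 0.555 with an estimated correlation), with Phlda3 at 0.66 and Aen at 0.49. They had 0.095 with the slide as a block, where they no longer passed, 0.087 within slide 2 and 0.025 within slide 3. Genes of the unfolded protein and integrated stress responses were higher with 0.16 over 23 (adjusted p = 0.00226; adjusted p = 0.555 with an estimated correlation), with Atf5 at 0.57 and Pdia6 at 0.67. They had 0.13 with the slide as a block, 0.22 within slide 2 and -0.045 within slide 3. No gene of these 5 metabolic and stress lists passed adjusted over the list alone, and in the same arrays the oligodendrocyte and astrocyte lists were also higher. The other probe of Hmgcs1 differed by -0.26, the 2 others of Cycs by -0.013 and 0.13, the 4 others of Homer1 by 0.45, 0.27, 0.013 and -0.031, and the 3 others of Rps24 by 0.28, 0.20 and 0.18. With the authors' own values the calls of antigen presentation, astrocytes, CA1, synapse, activity-regulated genes, neuropeptides, and unfolded protein and integrated stress also ended. Microglia (0.18) and choroid plexus and ependyma genes (0.25) newly passed as higher there, and dentate gyrus genes (-0.18) as lower. The array design places the probes used for Rps24, Cycs and Aen on chromosomes 1, 19 and 4, which do not hold these genes themselves, so signal from near-identical copies is not separated here.

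The remaining lists did not pass. Genes of CTCF and cohesin had a median of 0.13 over 11 genes (camera adjusted p = 0.0663), with Stag1 at 0.49 and at 1.097 by a second probe and Mau2 at 0.35, and passed as higher with the slide as a block (median 0.081). Cell cycle genes had -0.14 over 15 (adjusted p = 0.905), with Mcm2 at 0.97 and Cenpa at -0.33, and quantile normalization turned the median to 0.068. Imprinted genes had -0.019 over 37 (adjusted p = 0.749). Among them Calcr, the calcitonin receptor, fell, with a limma adjusted p of 0.0119, adjusted over the list alone. It was well above background on 4 WT and 0 CKO arrays and, with 75th percentile scaling, at least 1.81-fold lower in CKO. The log2 difference of Calcr with normexp background correction and quantile normalization was -0.23, short of that bound. For NF-kB targets, oligodendrocyte precursors, endothelium and pericytes and imprinted genes the median and mean were below 0 while the test leaned higher, since it sets a list against the other genes. For disease-associated microglia, blood and CA3 genes the mean was below 0 and the median above it.

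Other named genes also moved more than 1.5-fold with normexp background correction and quantile normalization, and none of them turned. Those lower in CKO were Bcl3 at -0.13, Ifit2 at -0.14, Calb1 at -0.23, Tdo2 at -0.24, Lilrb4a at -0.28, Pecam1 at -0.35, Slc4a1 at -0.13, Ahsp at -0.14 and Cenpa at -0.14. Those higher were Tac1 at 0.69, Egfl6 at 0.73, Mcm2 at 0.50, Emp1 at 0.95, Sod2 at 0.16, Chgb at 0.18, Mau2 at 0.22, Homer1 at 0.28, Cycs at 0.22 and Rps24 at 0.21. With the authors' own values Clu had 0.34, Psmb10 0.27, Aldoc 0.30, Syn1 0.31, Syn2 0.26, Homer1 0.24, Chgb 0.12, Mpped1 0.17, Rps9 0.32, Rps24 0.16, Cycs 0.17, Ndufb8 0.17, Sod2 0.12 and Mau2 0.22. There Bcl3 had -0.44, Ifit2 -0.44, Amigo2 -0.38, Slc4a1 -0.11, Ahsp -0.20 and Cenpa -0.11, while Egfl6 rose to 2.23, Mcm2 to 1.54 and Kl to 0.67.

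**Figure D2:**
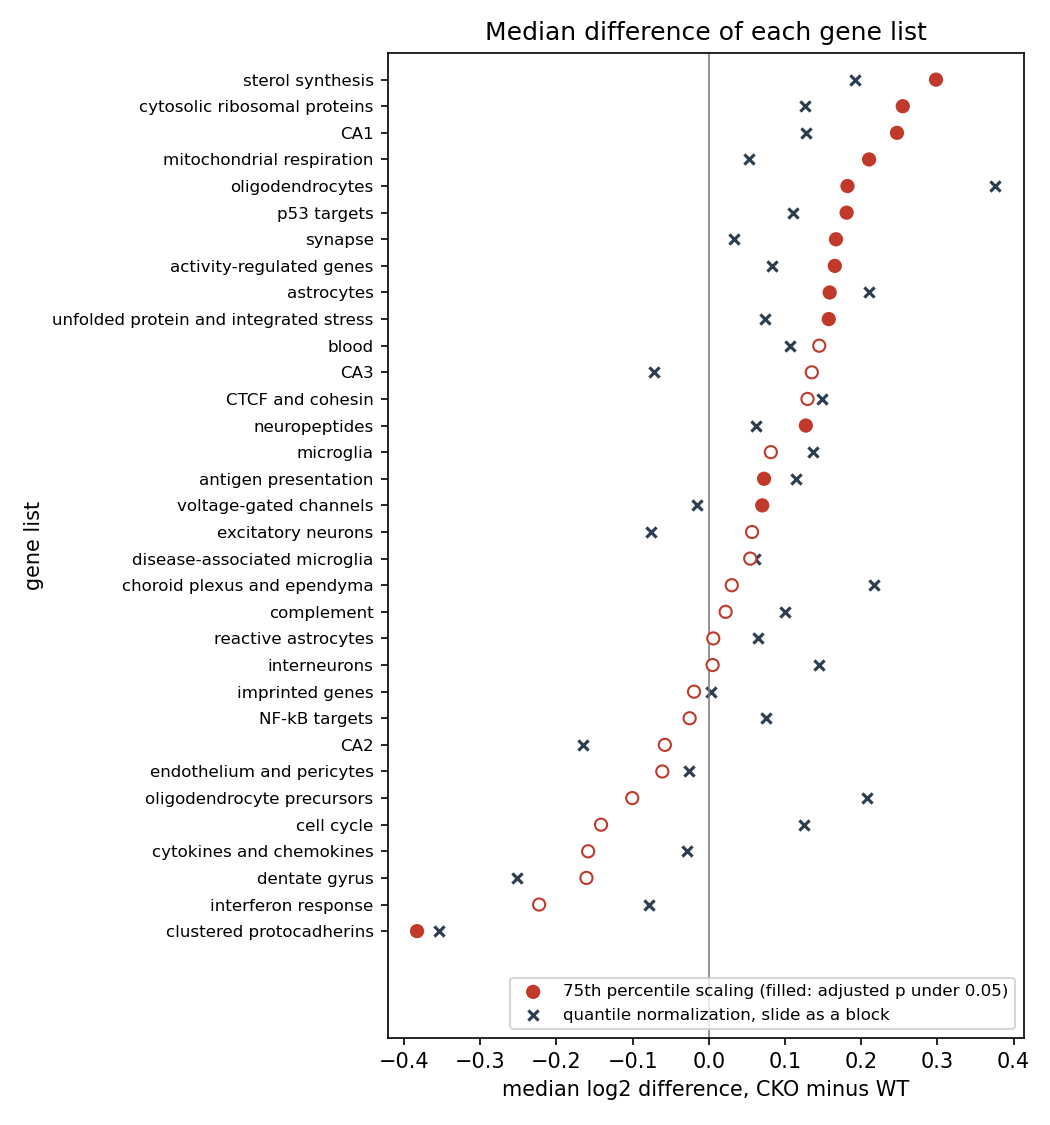
Median log2 difference between CKO and WT (horizontal axis) of each of the 33 gene lists; circles use 75th percentile scaling and are filled where the camera adjusted p with a preset correlation was under 0.05, and crosses use quantile normalization with the slide as a block. The clustered protocadherins lay at -0.38 and -0.35, the lowest under both, and oligodendrocytes at 0.18 and 0.38.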

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

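The tests of the slide and of CKO 3 for the protocadherins, the look at splits that keep each slide's numbers, and the tests of 3 of the higher lists apart from the rest were chosen after the results were seen. The limit of the comparison with signal-matched lists, for the lists higher in CKO, was tightened after its value was seen.

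In 16 of 234 groups of 4 values, 1 array lay far from the other 3, by Dixon's ratio of the gap to the range, and chance gives about 1 in 20 such groups. All values are normalized log2 signals. CKO 4 stood apart for Zfhx3 (-2.53, others -4.54 to -4.33), Mau2 (1.76, others 2.03 to 2.08), Pcdhb22 (-5.06, others -7.35 to -7.26), Aldoc (3.19, others 3.84 to 3.96), Rps9 (3.58, others 3.79 to 3.82) and the median of reactive astrocyte genes (-1.35, others -1.79 to -1.74). CKO 3 stood apart for Tpbg (-2.31, others -1.93 to -1.90), Pecam1 (-4.29, others -3.08 to -2.86), Phlda3 (0.098, others -0.71 to -0.67) and the median of excitatory neuron genes (3.19, others 2.65 to 2.73). CKO 2 stood apart for Etfdh (-1.87, others -1.096 to -1.002) and Mcm2 (-4.79, others -3.15 to -2.85). WT 4 stood apart for Vgf (1.93, others 1.429 to 1.496), Atf5 (2.51, others 1.81 to 1.90) and the median of imprinted genes (-0.12, others 0.42 to 0.52), and WT 3 for the median of astrocyte genes (0.066, others 0.00037 to 0.010). For the imprinted genes CKO 3 (-0.085) and CKO 4 (-0.089), also on slide 3, lay near WT 4, and CKO 1 (0.31) and CKO 2 (0.45) did not. That difference follows the slide, and slide 3 holds no other WT array.

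The 8 arrays can be split into 4 and 4 in 35 ways, and 12 of these, the real one included, gave at least as many genes past the threshold as the 1 gene between the genotypes, so chance cannot be excluded for that count. The highest of the other splits gave 3034 genes. It set the arrays of slide 2 against those of slides 1 and 3 and points to a structure of the samples by slide. With the slide as a block 1 gene passed between the genotypes. For the 14 lists called, 6 of the 35 splits called at least as many, up to 17 in another split, and the median over the splits was 8. Chance cannot be excluded for that count either.

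Clustered protocadherins were lower in CKO, by a median of -0.38. A difference that depends on signal may account for part of it, but not for all. Signal-matched random lists had a median of -0.12 (central 95% -0.26 to 0.029), and the percentile of the protocadherin median among them was 0. With quantile normalization the protocadherin median was -0.28. CKO 3 alone does not account for the difference, with a camera p of 3.38e-15 without it. Nor does the slide, with a camera p of 2.18e-07 with the slide as a block. Yet 3 of the 35 splits, the real one included, gave a camera p as small as the real 4.65e-08, down to 9.83e-13, so chance is not excluded; both of the others exchanged CKO 3 with a WT array of slide 2. Of the 18 splits that keep each slide's numbers the real one gave the smallest p (the next 1.45e-07), too few splits for a share under 0.05, and loss of CTCF remains a hypothesis next to chance.

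For the 13 lists called higher in CKO, 8 were still called higher without CKO 3, the array with the fewest probes above background, and the medians of 7 lay above the central 95% of signal-matched random lists; this met the limit first set against a signal-dependent difference, a majority, but by less than the binomial spread, and the limit was changed for that reason with the value known. For 3 of them (sterol synthesis, oligodendrocytes and cytosolic ribosomal proteins) the call held in each of these checks. All kept it with quantile normalization, though the median of the ribosomal proteins fell from 0.25 to 0.13. The lowest percentile was 99.4, and the largest camera adjusted p was 3.59e-04 without CKO 3 and 1.27e-04 with the slide as a block. The 3 lists were picked by these same values, so their passing is no separate evidence against signal, CKO 3 or the slide. Genotype, chance, the authors' scaling, which ended the call of the ribosomal proteins, and RNA of glia in the immunoprecipitate, which was not tested, also stay open for these 3. The call of oligodendrocytes ended without WT 4 (median 0.099). Astrocytes met the limits of a first run too, at the 97.7th percentile and a camera adjusted p of 0.0492 with quantile normalization. They kept their call without CKO 3 and with the slide as a block. They were set apart by an adjustment of the percentiles over the 13 lists, added with these values seen (0.0865 two-sided, 0.0433 one-sided). By that adjustment a signal-dependent difference is left open for them by a narrow margin. Quantile normalization brought the median of the dimmest genes from -0.52 to -0.067, and the astrocyte median from 0.16 to 0.15. Before it, lists matched to the astrocytes on signal had a median of 0.011 (central 95% -0.140 to 0.156). At the signal of the astrocyte genes it therefore had little to remove. The astrocyte median was 0.17 with normexp and quantile normalization and 0.21 with quantile normalization and the slide as a block, called in both. For that reason the small change under these settings cannot decide whether the astrocyte difference depends on signal. The authors' values ended the call of astrocytes (median 0.19, camera adjusted p = 0.103). For the other 9 an effect of genotype and these array differences cannot be told apart, since each lay within the central 95% of signal-matched lists or lost its call without CKO 3.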

How the results depend on the processing

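Quantile normalization with the slide as a block was chosen after seeing the data; the other settings were fixed before the data were examined. Beyond the results that answer a comparison, 2684 results under an alternative kept their direction and side of the threshold, 82 passed it newly, 120 no longer passed and 71 reversed. The cause was not tested, except that fewer arrays within a slide, in males or with an array left out leave less to test with. Even so, genes at an unadjusted limma p under 0.05 numbered 3940 without WT 4, 2539 without CKO 2 and 1673 without CKO 4. With all arrays they numbered 1567, and leaving out any other array gave 844 to 1367. Ctcf was lower and short of the adjusted threshold under every setting that tested it. The authors' values moved the median over all genes from -0.078 to 0.025. Signal over background limits the dim genes, and most of all on CKO 3.

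With quantile normalization the genes changed were 0 (lower in CKO 0), and the lists whose test against the other genes turned were, with their medians, cytokines and chemokines -0.061, CA2 -0.073, imprinted genes -0.0062 and cell cycle 0.068. In this part lists are given by that test, and a median may keep its sign where the test turned. With normexp and quantile 4 genes changed, 3 of them higher, and cytokines and chemokines had -0.026, CA2 -0.052, voltage-gated channels 0.013, imprinted genes -0.0064 and cell cycle 0.027. With the authors' series values 0 genes changed (lower 0) and 7 lists were called, and cytokines and chemokines had 0.017, excitatory neurons -0.021, CA3 -0.067, voltage-gated channels -0.019, imprinted genes -0.053 and cell cycle 0.18. Quantile normalization with the slide as a block gave 0 genes changed (lower 0), cytokines and chemokines -0.028, interferon response -0.078, endothelium and pericytes -0.026, CA3 -0.072, voltage-gated channels -0.016, imprinted genes 0.0025 and cell cycle 0.13.

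With no filter on dim probes 2 genes changed, both lower (2), and cell cycle had -0.093. With probes well above background on all 8 arrays 5 genes changed, 5 higher and 0 lower, and CA2 had 0.070. The mean of a gene's probes gave CA2 -0.058, and each probe tested gave 0 changed and 0 lower. A trended and robust prior variance gave 4 genes changed, 4 higher and 0 lower, and cytokines and chemokines -0.16. Array weights gave 11 genes changed, 7 higher and 4 lower, NF-kB targets -0.071 and CA2 -0.086. Without members of more than 1 list CA2 had 0.062. The estimated correlation called 0 lists, and fry 1 list, with a direction opposite to camera's for NF-kB targets (-0.025), reactive astrocytes (0.0058), endothelium and pericytes (-0.061) and imprinted genes (-0.019).

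The slide as a fixed block gave interferon response -0.14, endothelium and pericytes -0.071, CA3 0.041 and cell cycle -0.050. As a random block it gave 13 genes changed, 8 higher and 5 lower, and cell cycle -0.090. Within slide 2 there were 0 genes changed (lower 0), with NF-kB targets -0.050, interferon response -0.071, blood -0.082 and cell cycle -0.17. Within slide 3, where WT 4 is alone and assumed to vary like the others, there were 1 gene higher, 0 lower and 4 lists called, with cytokines and chemokines -0.020, endothelium and pericytes -0.10, CA3 -0.081, unfolded protein and integrated stress -0.045, cell cycle 0.054, Sod2 -0.012, Ahsp 0.056 and Cenpa 0.046. Sex as a covariate gave 3 genes changed, 2 higher. In males only 0 genes changed (lower 0), with endothelium and pericytes -0.068 and cell cycle -0.096.

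Medians also changed sign where the test did not turn. With quantile normalization these were NF-kB targets 0.076, oligodendrocyte precursors 0.032, endothelium and pericytes 0.047, excitatory neurons -0.013 and CA3 -0.0033, and with normexp and quantile NF-kB targets 0.028, oligodendrocyte precursors 0.014, endothelium and pericytes 0.011 and CA3 -0.0099. Median scaling gave NF-kB targets 0.066, endothelium and pericytes 0.031, CA2 0.034 and imprinted genes 0.072, and the authors' values NF-kB targets 0.10, oligodendrocyte precursors 0.051 and endothelium and pericytes 0.12. The slide as a fixed block gave NF-kB targets 0.019, disease-associated microglia -0.0037, oligodendrocyte precursors 0.13 and imprinted genes 0.039, as a random block imprinted genes 0.026, and with quantile normalization NF-kB targets 0.075, oligodendrocyte precursors 0.21 and excitatory neurons -0.076. Within slide 2 they were reactive astrocytes -0.037, oligodendrocyte precursors 0.22, where that list newly passed as higher, and imprinted genes 0.054. Within slide 3 they were NF-kB targets 0.12, excitatory neurons -0.010 and voltage-gated channels -0.021. Probes above background on all 8 arrays gave NF-kB targets 0.0015 and interneurons -0.0080, the mean of probes complement -0.032 and disease-associated microglia -0.036, array weights disease-associated microglia -0.028, reactive astrocytes -0.013, oligodendrocyte precursors 0.009985 and imprinted genes 0.046, and males only complement -0.073. Without members of more than 1 list they were NF-kB targets 0.0015, complement -0.013, interneurons -0.030 and excitatory neurons -0.011.

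With the replicate block 0 genes changed (lower 0), 16 lists were called and cell cycle had -0.14. Deviations of mice with the same number correlated at -0.32, 0.39, -0.42 and 0.068, and no WT mouse correlated best with its own number, so the mice share only a number and no pairing was used.

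With each array left out in turn the genes changed ran from 0 to 2 (lower in CKO 0 to 2), Ctcf from -0.995 to -0.76 and the lists called from 12 to 17. The 1 gene count fell to 0 without WT 2, WT 3, WT 4, CKO 2 or CKO 3 and rose to 2 without CKO 4. List medians ran from -0.11 to 0.035 for NF-kB targets, -0.34 to -0.021 for the interferon response, -0.13 to 0.069 for endothelium and pericytes, -0.031 to 0.35 for blood, -0.18 to 0.052 for CA2, -0.027 to 0.38 for activity-regulated genes, -0.043 to 0.038 for imprinted genes and -0.33 to 0.045 for cell cycle. They also changed sign for complement (-0.11 to 0.14), microglia (-0.028 to 0.12), disease-associated microglia (-0.077 to 0.092), reactive astrocytes (-0.097 to 0.081), oligodendrocyte precursors (-0.14 to 0.12), choroid plexus and ependyma (-0.018 to 0.19), interneurons (-0.043 to 0.087), excitatory neurons (-0.041 to 0.095) and voltage-gated channels (-0.026 without CKO 3 to 0.14 without WT 4).

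Other medians of called lists moved more than 1.5-fold, in sterol synthesis to 0.18 without CKO 3, p53 targets to 0.069 without CKO 3 and 0.11 without WT 2, CA1 to 0.13 without CKO 3, and synapse to 0.099 without CKO 3 and 0.11 without WT 1. Oligodendrocytes moved to 0.087 without CKO 2, 0.099 without WT 4, 0.11 without WT 2 and 0.30 without WT 1, astrocytes to 0.075 without CKO 1, and neuropeptides to 0.055 without WT 2, 0.067 without CKO 3 and 0.20 without WT 3. Unfolded protein and integrated stress moved to 0.27 without WT 4 and 0.26 without CKO 4, antigen presentation to 0.039 without WT 4, 0.12 without WT 1 and 0.11 without CKO 2, activity-regulated genes to 0.10 without WT 2, 0.28 without CKO 1 and 0.38 without CKO 4, and voltage-gated channels to 0.11 without CKO 2. Calls ended without CKO 3 for CA1, activity-regulated genes, voltage-gated channels, neuropeptides and p53 targets, without WT 4 for oligodendrocytes and antigen presentation, without CKO 2 for antigen presentation, without CKO 1 for astrocytes, and without WT 2 for activity-regulated genes, neuropeptides and p53 targets, among these.

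Of 28 settings, calls and directions held in 27 for clustered protocadherins, 26 for sterol synthesis, 24 for oligodendrocytes and for cytosolic ribosomal proteins, 23 for mitochondrial respiration and for unfolded protein and integrated stress, 22 for astrocytes, 21 for synapse, 20 for CA1, 19 for p53 targets, 16 for activity-regulated genes and for neuropeptides, 13 for antigen presentation and 7 for voltage-gated channels. The adjusted p of the protocadherins ran from 1.12e-13 to 0.202 over these settings.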

Other observations

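The tests of positions along the genome were chosen after the gene values were seen.

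Genes with an unadjusted limma p under 0.005 were counted in 266 windows of 10 Mb (mm9). The window from 30 to 40 Mb of chromosome 18 held 8 among 197 genes, 7 of them lower in CKO (hypergeometric test, adjusted p = 0.00161). The 8 included the protocadherins Pcdha12, Pcdhb16, Pcdhb21 and Pcdhb22, and outside that cluster Fchsd1 at 0.84 and 1700086O06Rik at -2.39. Neighbouring genes are not independent, and no other window passed. Next in order was 70 to 80 Mb of chromosome 3, where 3 of 44 genes were higher in CKO (adjusted p = 0.175), namely Etfdh, 4930579G24Rik at 1.17 and Tmem144 at 1.102.

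Several named genes lie near Ctcf on chromosome 8, and a hypothesis was that a stretch of donor chromosome retained around the floxed allele may carry variants that alter nearby signals. It applies only if the controls lack that allele, as their labels say, whereas the series' design text describes them as loxP homozygotes. Within 15 Mb of Ctcf 5 of 369 genes, 1.36%, had an unadjusted limma p under 0.005, namely Ccl17, Ccdc113, Pdf, Zfhx3 and 4922502B01Rik, 3 of them higher and 2 lower in CKO, against 0.480% elsewhere. Of windows of that size centred on a gene 4.08% were at least as rich, but the window and limit were picked with these genes in view. Therefore 20 combinations of window and p limit were run. In 8 of the 20 the share near Ctcf was among the highest 5% of windows centred on a gene, and the share of windows at least as rich ran from 0.417% to 23.3%. The result depended on the p limit. At 0.001, with 3 to 5 genes near Ctcf, that share was 0.417% to 1.34% over the window sizes, and at 0.05 it was 3.43% to 23.3%. The combinations share genes and are not independent. Chance placement is thus not excluded. Nothing here separates such a stretch from an effect of CTCF on its neighbours, since the mice's genotypes around Ctcf were not analysed here.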
